A study of Homo sapiens with 4 samples.

How the data were processed

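RNA from SKOV3 cells, an established human ovarian carcinoma line, was measured on 4 Affymetrix expression arrays, 2 from untreated control cells and 2 from cells treated with rhSTIP1. The name rhSTIP1 was read as recombinant human STIP1, the HSP70 and HSP90 organizing cochaperone. Dose and duration of treatment are not given in the sources used here. Per the labels, total RNA was extracted with TRIZOL and labelled with biotin by the standard protocol of the array's maker. The series title names a pathway spelled SAMD1/5, which was read as SMAD1/5, the signal transducers of the BMP receptors, because STIP1 is known to act on that pathway.

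The deposited values are linear probe set intensities, made with MAS5 in Affymetrix Expression Console 1.1 per the submitters' processing notes. MAS5 summarises the probes of each probe set on 1 array at a time and scales each array to a common target. In the deposited table the mean signal after trimming 2% of probe sets from each end was 500.1 on every array, and no log had been taken. MAS5 signals of dim probe sets vary widely between arrays. The table used here holds no detection calls, so a dim signal could not be told from background.

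The table held 54675 probe sets, of which 62 were control probe sets and were used only to describe RNA quality. Of the other 54613, 41091 had exactly 1 gene symbol in the platform annotation, 1801 had several and 11721 had none. The gene identifiers of 41037 of those with 1 symbol were found in the current gene table, built on the GRCh38.p14 assembly, and 0 symbols changed. No coordinates are given, because the array values carry no genome build. Each of 19775 genes was represented by its probe set with the highest mean signal over the 4 arrays, among probe sets with exactly 1 symbol. A gene was tested where that mean reached 69.4, the median of the means of all probe sets other than controls, which kept 12296 genes and left out 7479.

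The rhSTIP1 arrays were compared with the control arrays by lmFit and eBayes of limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(signal + 16), two-sided, with Benjamini-Hochberg adjustment and no further scaling. Each gene had 2 residual degrees of freedom, to which the shared estimate of the spread added 5.56. A fold change is on the log2(signal + 16) scale and understates the change of dim genes. The ± values are standard errors of the log2 fold change from that model. With 2 arrays against 2, an exact two-sided permutation test of a single gene cannot give a p below 0.333. The count of genes whose arrays did not overlap between groups and that differed by at least 1.5-fold was therefore given beside the tests, with the same count for the 2 other ways to split the arrays 2 against 2.

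The comparison, its model, 18 pathway lists, 6 lists of cell type markers, the rule for named genes and the alternatives were chosen before the data were examined. The lists held 526 symbols, of which 1 was renamed through its synonyms, 480 had a usable probe set and 424 were tested. Pathway lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 18 lists, and again with an estimated correlation and with fry, whose directional test asks whether a list moves one way and whose mixed test asks whether it moves at all. Named genes were 11 genes of the SMAD1/5 pathway, the 12 higher and 12 lower genes with the smallest unadjusted p among those separated by at least 1.5-fold, leaving out names that are only locus or open reading frame codes, and up to 4 members of each pathway list with the smallest unadjusted p. Any other gene is said to have been chosen after its values were seen.

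The steps were tested on simulated data with 12296 genes and 2 arrays against 2, with 200 genes changed. At an adjusted p of 0.05, 5 of 67 genes changed 2-fold (7.46%), 51 of 67 changed 4-fold (76.1%) and 63 of 66 changed 16-fold (95.5%) were recovered, with 5 false calls. A simulated shifted list was found and 0 of 18 unshifted lists were called. The simulated genes were drawn independently of each other, so false calls of lists whose genes move together were not tested. In the real data the estimated correlation between genes reached 0.92, in the mitosis list. The number of arrays limits the precision of every value. Alternatives covered the pseudocount, the filter, the scaling, the choice of probe set, the replicate number as a block, the eBayes settings, the list test and leaving out each array, which assumes that the lone array of a group varies like the 2 of the other group.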

Results

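Gene expression was measured in SKOV3 ovarian carcinoma cells with and without rhSTIP1, the recombinant form of a cochaperone that cells also secrete. Each group had 2 arrays, and the labels do not say whether the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Median signals were 66.0 and 79.2 on the control arrays and 69.0 on both rhSTIP1 arrays. Pearson correlations over the 12296 tested genes, which are not independent replicates, ran from 0.952 to 0.979 between arrays, and no arrays were duplicates. The 3′ to 5′ signal ratio of ACTB, which rises when RNA is degraded, was 2.74 and 2.45 in the controls, 2.62 in rhSTIP1 array 1 and 8.79 in rhSTIP1 array 2. The same ratio of GAPDH lay between 0.987 and 1.32 on all 4 arrays.

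The series title names the SMAD1/5 pathway, in which the receptor ACVR1 and the transducers SMAD1, SMAD5 and SMAD4 raise transcription of the ID genes, inhibitors of basic helix-loop-helix transcription factors, and of the inhibitory SMAD6 and SMAD7. All 4 ID genes and SMAD7 were higher in both rhSTIP1 arrays than in either control. ID3 had signals of 499.6 and 189 in the controls and 12430.5 and 4643 with rhSTIP1, a log2 fold change of 4.55 ± 0.55 or 23.4-fold. ID1 went from 12081 and 3734 to 31894 and 22035, a log2 fold change of 1.98 ± 0.48. ID2 was 3.27-fold higher, at 1.71 ± 0.26, and ID4 2.57-fold higher, at 1.36 ± 0.21. SMAD7, which had signals of 695 and 564 in the controls, reached 1804 and 1615 with rhSTIP1, 1.42 ± 0.24. With 1 array left out the log2 fold change of ID3 ran from 3.84 (without rhSTIP1 array 1) to 5.26 (without rhSTIP1 array 2) and that of ID1 from 1.13 (without control array 2) to 2.82 (without control array 1).

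The transcripts of the components upstream of these genes showed no such separation. The arrays measure transcripts only, so the values below do not show the amount or activity of the proteins. STIP1 itself had a log2 fold change of −0.17 ± 0.34, ACVR1 0.19 ± 0.30, SMAD1 −0.14 ± 0.23, SMAD5 −0.02 ± 0.24 and SMAD4 −0.36 ± 0.27, and the arrays of both groups overlapped for each. SMAD6 was higher in both rhSTIP1 arrays, at 540.3 and 339 against 331 and 305, but by only 0.41 ± 0.30. Of the 11 genes, 5 passed limma's test adjusted over the list alone (adjusted p from 5.1e-04 for ID3 to 0.00866 for ID1). Over all genes tested 0 passed, and ID3 had an adjusted p of 0.19. These genes belong to the pathway that the title names, and it is not stated whether that naming came from these arrays. The tests over the list alone are therefore not independent evidence. Without rhSTIP1 array 1, 4 of the 11 passed over the list alone and ID1 had an adjusted p of 0.0612.

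**Figure D1:**
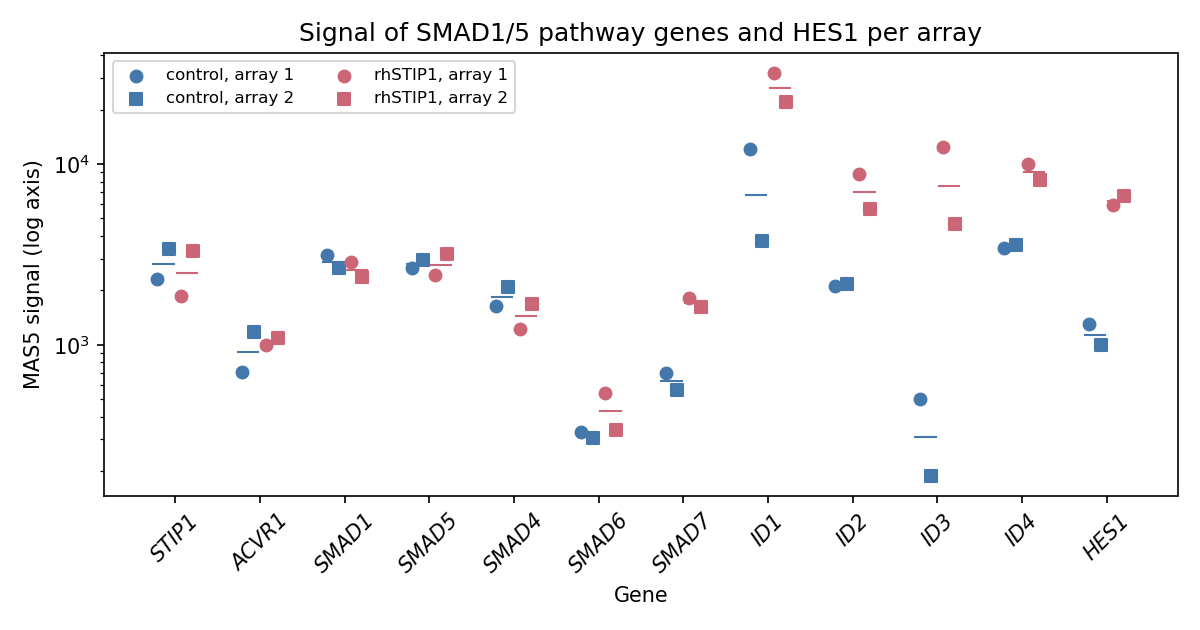
MAS5 signal (log axis) of the 11 SMAD1/5 pathway genes and HES1 on each array, with control in blue, rhSTIP1 in red, array 1 as circles, array 2 as squares and group means on the log2(signal + 16) scale as bars. ID3 signals were 499.6 and 189 in the controls and 12430.5 and 4643 with rhSTIP1, whereas the arrays of both groups overlapped for STIP1, ACVR1, SMAD1, SMAD5 and SMAD4.

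Known target genes of SMAD1/5 rose as a list, with a median log2 fold change of 0.33 over 18 tested members (camera, adjusted p = 1.2e-08 with the preset correlation). With an estimated correlation the adjusted p was 0.61, and the p before adjustment was 0.0722. Of the 18 members 12 had a fold change above 0 and 6 below, and 7 passed the test adjusted over the list alone, all higher. The arrays were separated for 10 members that were higher and 3 that were lower (HEY2, GATA2 and MSX1). ID1, ID2, ID3, ID4, SMAD6 and SMAD7 are also among the 11 pathway genes above, so the rise of the list largely repeats theirs. The members outside those genes did not move one way. HES1, SNAI2, DLX2, SMAD9, MSX2 and ATOH8 were above 0. HEY2 (−0.46), GATA2 (−0.33), BAMBI (−0.24), HEY1 (−0.18), MSX1 (−0.17) and RUNX2 (−0.15) were below. Of the 7 that passed, only HES1 and SNAI2 were not among the 11 pathway genes. HES1, a repressor that Notch signalling also drives, had signals of 1305 and 993 in the controls and 5917 and 6655 with rhSTIP1, 2.45 ± 0.24 or 5.45-fold. The title names this pathway, and it is not stated whether that came from these arrays. Neither the direction of the list nor its tests are therefore independent evidence. Receptors and other components of BMP signalling did not pass (17 members, median 0.06, adjusted p = 0.788), and 0 of them had an unadjusted p under 0.05. SMURF2, a ubiquitin ligase that targets SMAD proteins, had a log2 fold change of 0.27 ± 0.22, GDF15 −0.50 ± 0.57 and RGMB 0.18 ± 0.27.

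TGF-beta target genes rose by a median of 0.13 over 18 members, 15 of them with a fold change above 0 (adjusted p = 0.0105, and adjusted p = 0.61 with an estimated correlation). SKIL, a repressor of SMAD signalling, was higher in both rhSTIP1 arrays at 0.59 ± 0.25. CCN2 had 1.48 ± 0.79 with overlapping arrays, and NEDD9 and PMEPA1 had 0.82 ± 0.44 and 0.68 ± 0.37. The call was lost without control array 2 (median 0.07, adjusted p = 0.896) and without rhSTIP1 array 2 (median 0.22, adjusted p = 0.152), while the median was 0.37 without control array 1 and 0.23 without rhSTIP1 array 1. It was also lost with the mean of each gene's probe sets (adjusted p = 0.075).

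Across all genes 700 were separated by at least 1.5-fold, meaning that the arrays of the groups did not overlap and the group difference was at least 1.5-fold, 234 higher and 466 lower with rhSTIP1. The share that was lower, 66.6%, depended on the setting. It was 57.3% with median centring, 59.4% with quantile normalization and 71.0% with a filter at the 70th percentile. Without control array 2 it was 52.2%, and without rhSTIP1 array 1 it was 53.2%. The higher genes with the smallest p included, besides HES1, ID2, ID3, ID4 and SMAD7, the thrombin receptor THBD (146 and 253 in the controls, 821 and 725 with rhSTIP1, 1.92 ± 0.31), the ERK phosphatase DUSP5 (1.61 ± 0.31) and NAB2 (1.37 ± 0.27), a corepressor of EGR transcription factors. HMOX1, which breaks down heme, had signals of 135 and 361 in the controls and 855 and 1329 with rhSTIP1, 2.18 ± 0.44. FAM43A (1.87 ± 0.33), FOSB (3.26 ± 0.59) and ANHX (2.35 ± 0.44) completed the 12, the last 2 with dim controls. The lower genes were led by CHAC1, an enzyme that degrades glutathione, with signals of 2975 and 2403 in the controls and 446 and 411 with rhSTIP1, −2.60 ± 0.24. Most of the others act in the cell cycle or in DNA repair. They were HJURP (−2.27 ± 0.33), which loads centromeric histone, E2F8 (−1.99 ± 0.35), NEIL3 (−1.59 ± 0.27), ESPL1 (2.84-fold lower), CDK1 (−1.41 ± 0.22), CDCA5 (−1.38 ± 0.25), SPAG5 (−1.37 ± 0.28), CCNA2 (−1.34 ± 0.28), MYBL2 (−1.25 ± 0.24) and E2F7 (−1.16 ± 0.23). The stress transcription factor DDIT3 was also among them, at −1.39 ± 0.28.

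No single gene passed limma's test over all genes, 0 of 12296 at an adjusted p of 0.05, and the smallest adjusted p was 0.0689, for CHAC1 and HES1. At an unadjusted p under 0.05 there were 452 genes, 128 higher and 324 lower. Other settings of the pseudocount, filter, scaling, probe sets and eBayes called between 0 and 2 genes, and leaving out 1 array called 3 without control array 1, 6 without control array 2 and 0 without either rhSTIP1 array. With 1 array left out, here and for the lists, the spread comes from the other group's 2 arrays alone and the lone array is assumed to vary like them, so such calls are no independent check. The groups did not overlap, at any size of change, for 3557 genes or 28.9%, where chance gives 33.3%, against 48.5% between array 2 and array 1 of each group and 22.6% in the crossed split of control array 2 and rhSTIP1 array 1 against the other 2. Every gene falls in exactly 1 of these 3 splits, so a large share in one lowers the others. Setting array 2 of each group against array 1 separated 1397 genes by at least 1.5-fold, more than the 700 for rhSTIP1, and the crossed split separated 411. With 1 array left out, where fewer values need to be apart, the count was 1062 without control array 1, 1979 without control array 2, 1548 without rhSTIP1 array 1 and 1424 without rhSTIP1 array 2.

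Mitosis genes fell together. All 32 members had a log2 fold change below 0, with a median of −1.30 and quartiles of −1.45 and −1.10 (adjusted p = 1.4e-36 with the preset correlation, and adjusted p = 0.61 with an estimated correlation). For 23 of them both rhSTIP1 arrays lay below both controls and the group difference was at least 1.5-fold, and 22 passed the test adjusted over the list alone, against 0 over all genes. CDK1, the kinase that drives entry into mitosis, had signals of 6202 and 5026 in the controls and 2076 and 2095 with rhSTIP1. The kinesin KIF2C was lower by −1.41 ± 0.30 and the centromere motor CENPE by −1.35 ± 0.30. The controls themselves differed over this list, control array 2 lying below control array 1 by a median of −1.12, and rhSTIP1 array 1 lay below control array 2 by −0.39. The median was −0.73 without control array 1 and the list was called with each array left out in turn.

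**Figure D2:**
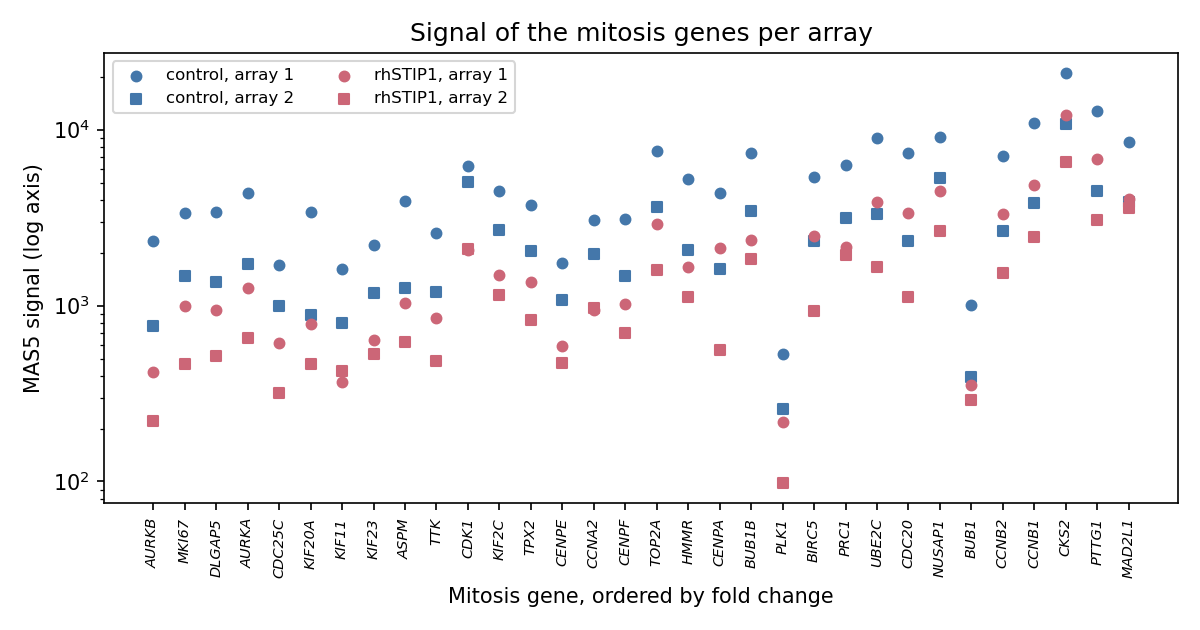
MAS5 signal (log axis) of the 32 mitosis genes on each array, ordered by fold change, with control in blue, rhSTIP1 in red, array 1 as circles and array 2 as squares. Control array 1 was the highest array for these genes, and for 23 of the 32 both rhSTIP1 arrays lay below both controls with a group difference of at least 1.5-fold.

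DNA replication genes also fell, by a median of −0.50, and all 29 members had a log2 fold change below 0 (adjusted p = 2.3e-10, and adjusted p = 0.61 with an estimated correlation). The arrays were separated by at least 1.5-fold for 11 of them and 0 passed adjusted over the list alone. RRM2, a subunit of ribonucleotide reductase, had signals of 5460.1 and 4093 in the controls and 772 and 2394 with rhSTIP1, −1.78 ± 0.48. TYMS had −0.93 ± 0.31, CDT1 −0.97 ± 0.33 and RFC4 −0.68 ± 0.22. Without rhSTIP1 array 1 the median was −0.07 and the call was lost (adjusted p = 0.147), and without rhSTIP1 array 2 it was −0.81.

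Immediate-early and ERK target genes rose by a median of 0.19 over 26 members, 16 above 0 and 10 below (adjusted p = 0.00848, and adjusted p = 0.61 with an estimated correlation). The 4 that passed adjusted over the list alone were FOSB, DUSP5, JUNB (1.08 ± 0.23) and KLF10 (0.94 ± 0.23), all higher. FOSB, a subunit of the AP-1 transcription factor, was at 18.6 and 6.12 in the controls, under the level at which genes were tested, and at 444 and 137 with rhSTIP1. DUSP6, an ERK phosphatase induced by ERK, went the other way, at −1.46 ± 0.53, and was chosen after its values were seen. The median was −0.07 without rhSTIP1 array 2 (adjusted p = 0.395), the array with the high ACTB ratio, and 0.63 without rhSTIP1 array 1, and the call was also lost without control array 2 (adjusted p = 0.27).

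Genes of the ATF4 amino acid response fell, with a median of −0.10 and a mean of −0.30 over 24 members (adjusted p = 0.00893, and adjusted p = 0.61 with an estimated correlation). The change lay in a few of them. CHAC1, DDIT3 and DDIT4, an inhibitor of mTORC1 signalling, passed adjusted over the list alone, all lower, and DDIT4 had signals of 14491 and 12259.5 in the controls and 5610.4 and 1986 with rhSTIP1, −1.99 ± 0.43. ATF4 itself had −0.40 ± 0.14. The median was 0.07 without control array 2 (adjusted p = 0.929), −0.19 without control array 1 and −0.06 without rhSTIP1 array 1. By contrast, genes of the unfolded protein response rose by a median of 0.28 over 20 members (adjusted p = 6.3e-04, and adjusted p = 0.61 with an estimated correlation). DNAJB9, a chaperone of the endoplasmic reticulum, was 2.82-fold higher and MANF had 0.56 ± 0.26, and 0 members passed adjusted over the list alone. The median was 0.07 without control array 1 (adjusted p = 0.277) and 0.42 without control array 2. HSP90 and heat-shock chaperones, the partners of STIP1, did not pass (22 members, median 0.08, adjusted p = 0.387), nor did p53 target genes (20 members, median −0.03, adjusted p = 0.401). Of the latter 5 were separated lower and 5 higher. Among them SESN2 (−1.05 ± 0.26), GADD45A (−0.74 ± 0.19), PMAIP1 (−0.80 ± 0.25) and DDB2 (−1.26 ± 0.51) were lower in both rhSTIP1 arrays. PLK3 (0.65 ± 0.34), ZMAT3 (0.61 ± 0.35), CDKN1A (0.48 ± 0.26), BAX (0.30 ± 0.25) and PHLDA3 (0.28 ± 0.25) were higher in both and TNFRSF10B (−0.15 ± 0.19) was lower, all 6 chosen after their values were seen.

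NF-kappaB and inflammatory genes fell by a median of −0.62 over 20 members, 16 of them below 0 (adjusted p = 9.3e-04, and adjusted p = 0.61 with an estimated correlation). The chemokines CXCL1 and CXCL2 passed adjusted over the list alone. CXCL1 had signals of 16605 and 13826 in the controls and 3137 and 7572 with rhSTIP1, −1.63 ± 0.38, and CXCL2 had −1.86 ± 0.42. CXCL3 had −1.67 ± 0.54, whereas the cytokine LIF was higher in both rhSTIP1 arrays at 1.18 ± 0.40. Without rhSTIP1 array 1 the median was 0.16 and the call was lost (adjusted p = 0.564). It was −1.20 without rhSTIP1 array 2 and −0.32 without control array 1. The type I interferon response did not pass (22 members, median −0.03, adjusted p = 0.789), but it passed in opposite directions without rhSTIP1 array 1 (median −0.38, adjusted p = 0.00447) and without rhSTIP1 array 2 (median 0.35, adjusted p = 0.0105).

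Cholesterol synthesis genes fell by a median of −0.51 over 19 members, 17 below 0 (adjusted p = 0.00114, and adjusted p = 0.61 with an estimated correlation), but the arrays were separated for only 1, STARD4 (−0.83 ± 0.37). The controls differed by more than the groups did, control array 2 lying below control array 1 by a median of −1.25. The median was 0.13 without control array 1 (adjusted p = 0.273) and 0.10 without rhSTIP1 array 2 (adjusted p = 0.603), against −1.21 without control array 2 and −1.06 without rhSTIP1 array 1. Ribosomal protein genes rose by a median of 0.12, all 25 above 0 and 17 separated (adjusted p = 6.3e-04, and adjusted p = 0.61 with an estimated correlation). That call was lost without rhSTIP1 array 1 (adjusted p = 0.0997) and under quantile normalization (median 0.04, adjusted p = 0.411). Hypoxia and glycolysis genes (27 members, median 0.08, adjusted p = 0.441) and oxidative phosphorylation genes (27 members, median 0.06, adjusted p = 0.209) did not pass, although ANGPTL4 had 1.44 ± 0.60. The hypoxia list passed without control array 2 (median 0.22, adjusted p = 0.00796) and without rhSTIP1 array 1 (median 0.32, adjusted p = 0.00309), and its median was below 0 with either of the other arrays left out. The oxidative phosphorylation list passed without control array 1 (median 0.13, adjusted p = 0.0371) and without rhSTIP1 array 2 (median 0.17, adjusted p = 0.00189).

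Epithelial junction and ovarian carcinoma genes rose by a median of 0.17 over 23 members (adjusted p = 0.0399, and adjusted p = 0.61 with an estimated correlation), and 0 members had an unadjusted p under 0.05. The call was lost without control array 1 (median 0.03, adjusted p = 0.279), without rhSTIP1 array 2 (median 0.05, adjusted p = 0.395), with no filter (adjusted p = 0.0702), with a filter at the 70th percentile (adjusted p = 0.152), with quantile normalization (adjusted p = 0.207) and with the mean of each gene's probe sets (adjusted p = 0.374). Mesenchymal and matrix-remodelling genes did not pass (24 members, median −0.03, adjusted p = 0.494), but they passed with a median of 0.13 without control array 1 (adjusted p = 0.0132), −0.32 without control array 2 (adjusted p = 0.00254) and −0.22 without rhSTIP1 array 1 (adjusted p = 0.0286). PLAUR, the urokinase receptor, had 0.66 ± 0.25 and the matrix protein TNC −0.97 ± 0.40.

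**Figure D3:**
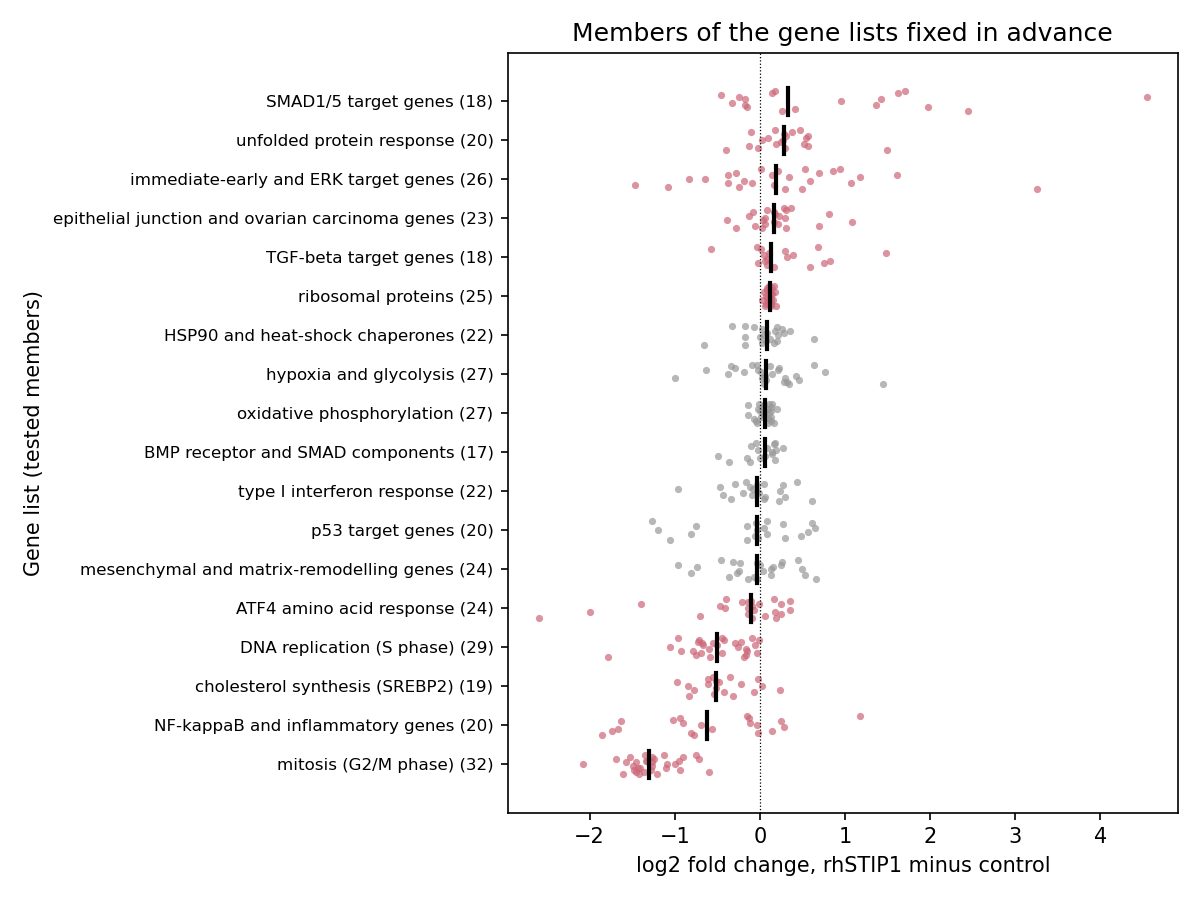
Log2 fold change, rhSTIP1 minus control, of every tested member of the 18 pathway lists, with black bars for list medians, red for lists with a camera adjusted p under 0.05 at the preset correlation and grey for the others. Medians ran from −1.30 for mitosis genes to 0.33 for SMAD1/5 target genes, whose highest member, ID3, had 4.55.

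Of the 18 lists 11 passed with the preset correlation, 6 up and 5 down, and 0 with an estimated correlation or with fry's directional test. With the estimated correlation the adjustment gave all 11 the same 0.61, although their p before adjustment differed. That camera p ran from 0.0722 for SMAD1/5 target genes to 0.425 for cholesterol synthesis genes, and was 0.113 for mitosis genes. In fry's mixed test 1 passed, the ATF4 list (adjusted p = 0.00851). Markers of other cell types that had a probe set were counted where they were above the level at which genes were tested. Fibroblast markers had 4 of 10 above it (median 0.47, the brightest being COL1A1 with a mean signal of 208). Leukocyte markers had 2 of 11 (median −0.06), endothelial markers 1 of 8 (0.23) and erythroid markers 2 of 4 (0.11). Mesothelial markers had 5 of 6 (−0.39) and keratinocyte markers 2 of 4 (−0.32). SFN, a keratinocyte marker that carcinoma lines also express, was the brightest of all at a mean of 4188. No marker passed the adjusted test, and KRT5, which is on both the mesothelial and keratinocyte lists, had −0.85 ± 0.36. The collagens among the fibroblast markers are also on the mesenchymal list, and MSLN and WT1 among the mesothelial markers are also on the ovarian carcinoma list.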

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

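The tests of scaling and of dividing cells on the mitosis genes were chosen after the result was seen, and the test without rhSTIP1 array 2 before it.

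In 4 measures from control probe sets that no comparison used, rhSTIP1 array 2 was at least 1.5 times above the highest control array. The 3′ to 5′ signal ratio of ACTB was 8.79, against at most 2.74 in the controls. The 3′ probe set of 18S ribosomal RNA was at 2543, against at most 1616. The 28S ribosomal RNA probe sets were at 7070.3 (5′) and 5399 (middle), against at most 2032.5 and 1954. Control array 2 was also above control array 1 for 18S ribosomal RNA, at 1616 against 398.

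The fall of the mitosis genes was weighed against these signs of RNA quality. Without rhSTIP1 array 2 the list's median was −1.04 and 32 of 32 members stayed below 0, which argues against degraded RNA on that array as the whole cause. The median log2 fold change over all tested genes was 0.02. MAS5 had already scaled each array to a common target, so that value is no check of the scaling. A uniform scaling error would move all genes alike, and the list's −1.30 against 0.02 argues against that kind of error only. The mitosis list's median was −1.30 under quantile normalization, but with so small a shift over all genes that setting had little room to move it. Quantile normalization did end the call of the ribosomal protein list. What stays open is the spread between cultures in the share of dividing cells. The controls differed over the list by −1.12, which is 0.863 of the difference between groups, and rhSTIP1 array 2 lay below rhSTIP1 array 1 by −0.77. Between arrays of the same number the median was −1.55 for number 1 and −1.06 for number 2. The labels do not say that the numbers pair the arrays, so spread between cultures cannot be told apart from an effect of rhSTIP1 on dividing cells.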

How the results depend on the processing

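All alternatives given here were chosen before the data were examined. Of the comparisons of single genes with other settings, 1204 kept their direction and side of the threshold, 55 newly passed it and 14 reversed. For list medians 183 were the same, 7 newly passed, 36 kept their direction but no longer passed and 26 reversed, 5 of which were of called lists that no longer passed either and 2 of uncalled lists that then passed (mesenchymal genes without control array 1 and interferon genes without rhSTIP1 array 2). Where a value moved, the cause was not tested unless fewer genes, arrays or a stricter minimum show it. Dim signals limit the rest, since no detection calls were used.

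Against 0 genes past an adjusted p of 0.05, 1 passed with a filter at the 70th percentile (CHAC1), 2 with median centring and 2 with robust eBayes (both CHAC1 and HES1), and 0 to 6 with 1 array left out. The labels give both groups the numbers 1 and 2 without saying that these pair the arrays, and the deviations of same-numbered arrays correlated over genes at r = 0.362. With the number as a replicate block, 247 genes passed, 63 higher and 184 lower, with 30 of the mitosis genes and 5 of the 11 pathway genes, and 1132 had an unadjusted p under 0.05. At an unadjusted p under 0.05 the other settings with all arrays gave between 350 (filter at the 70th percentile) and 878 (each probe set on its own) genes.

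Against 700 genes separated by at least 1.5-fold (234 higher, 466 lower), there were 2087 with no filter (855, 1232), 424 with a filter at the 70th percentile (123, 301), 1753 with each probe set on its own (564, 1189) and 229 at a 2-fold minimum (59, 170). A pseudocount of 64 gave 150 higher. Leaving out 1 array gave 1062 to 1979 (408 to 945 higher, 654 to 1034 lower). Of the lists, 11 passed with the preset correlation, 0 with an estimated correlation and 0 with fry's directional test, and 9 to 11 in the other settings. Of the pathway genes 5 passed over the list alone, and 4 without rhSTIP1 array 1.

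Without a filter BMP components were at −0.015. With a filter at the 70th percentile p53 targets were at 0.013 and interferon genes at 0.049, and with quantile normalization at 0.0092 and 0.0033. Median centring gave 0.0069 for mesenchymal genes, 0.012 for p53 targets, 0.012 for interferon genes and 0.025 for SMAD5. The mean of a gene's probe sets gave −0.054 for BMP components, 0.0081 for mesenchymal genes, 0.19 for SMAD4, 0.050 for GDF15 and −0.49 for KRT7. With 1 array left out, medians ran from −0.19 to 0.074 for ATF4 genes, −0.051 to 0.20 for BMP components, −0.039 to 0.14 for HSP90 and heat-shock chaperones, −1.20 to 0.16 for NF-kappaB genes, −1.21 to 0.13 for cholesterol synthesis, −0.14 to 0.32 for hypoxia, −0.066 to 0.63 for immediate-early genes, −0.32 to 0.13 for mesenchymal genes, −0.051 to 0.17 for oxidative phosphorylation, −0.084 to 0.049 for p53 targets and −0.38 to 0.35 for interferon genes. Fold changes ran from −0.59 to 0.25 for STIP1, −0.17 to 0.56 for ACVR1, −0.21 to 0.18 for SMAD5, −1.40 to 0.41 for GDF15, −0.0021 to 0.36 for RGMB, −1.12 to 0.017 for SQLE and −0.29 to 2.47 for ESRP1.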

Other observations

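The tests on the array number were chosen after the result was seen, and the test on the other NRF2 targets was set before their values were looked at, except for leaving out each array.

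Several genes of the oxidative stress response controlled by NRF2, none of which was on a list fixed in advance, were higher in both rhSTIP1 arrays, and they were chosen after their values were seen. Beside HMOX1 (2.18 ± 0.44) they were GCLC (0.72 ± 0.33), which makes glutathione, the exporter ABCC3 (0.81 ± 0.34) and the aldo-keto reductases AKR1C1 (0.71 ± 0.32), AKR1C2 (0.97 ± 0.27) and AKR1C3 (0.69 ± 0.21). For each of these genes control array 1 lay below control array 2, so the size of the difference rests in part on control array 1. GCLC, for example, had signals of 1939 and 3928 in the controls and 4711 and 4423 with rhSTIP1. AKR1C1 had 9948 and 21143 in the controls and 22690.5 and 24757 with rhSTIP1. The aldo-keto reductases are close paralogs whose probes may cross-hybridise, so their separate values are uncertain. As a hypothesis, a general rise of NRF2 targets would lift the others too, and of 15 other targets 13 were tested, with a median log2 fold change of 0.37. All 13 were above 0, for example SRXN1 (0.93 ± 0.41), UGDH (0.55 ± 0.24) and GCLM (0.51 ± 0.30), and 5 were separated (camera p = 1.7e-06 with the preset correlation and p = 0.167 with an estimated one, 0 with an unadjusted p under 0.05). The median rested in part on control array 1, without which it was 0.16 with 12 of 13 above 0, under the 0.2 set for the hypothesis, and it ran up to 0.56 without control array 2. The hypothesis therefore stays open, and it was found and tested on the same arrays.

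The arrays differed more by their number than by rhSTIP1. Setting array 2 of each group against array 1 separated 1397 genes by at least 1.5-fold, against 700 for rhSTIP1. Genes of cholesterol synthesis were lower in the arrays numbered 2, such as FDPS (a log2 difference of −1.54), DHCR7 (−1.71), HMGCS1 (−1.47), IDI1 (−1.43) and ACAT2 (−2.03), as was IGFBP2 (−2.51). CDH1 (2.05), WFDC2 (1.92), ESRP1 (1.73), LCN2 (2.05) and S100P (3.42) were higher there, and all of these were chosen after their values were seen.

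Degraded RNA on rhSTIP1 array 2 would leave the controls alike, but the difference between arrays 2 and 1 in the controls correlated over genes with that in the rhSTIP1 arrays (r = 0.362), and 2431 genes differed by at least 1.5-fold between the controls, against 2487 between the rhSTIP1 arrays. That argues against degraded RNA on that array alone as the whole cause. It does not cover an RNA difference shared by both arrays numbered 2, which was not tested. The 3′ probe set of 18S ribosomal RNA was at 398 (control) and 427 (rhSTIP1) on the arrays numbered 1. On those numbered 2 it was at 1616 and 2543. The 5′ probe set of 28S ribosomal RNA was at 503 and 947 on the former and 2032.5 and 7070 on the latter. Cells of another type in 1 pair of arrays cannot be told apart from other causes, because among the fibroblast, leukocyte, endothelial and erythroid lists only 1, that of fibroblasts, had 3 or more members above the filter, with a median difference of −0.0080. A shared day or culture state of the arrays with 1 number may be the source, but the labels give no date or batch and this was not tested.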
